A study of Mus musculus with 4 samples.

How the data were processed

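Liver endothelial cells were profiled by probe-based single-cell RNA sequencing in 4 libraries from female B6D2F1/J mice, the F1 hybrid of the B6 and DBA2 strains. Recipients had been given a syngeneic or an allogeneic haematopoietic stem cell transplant, and cells were collected 4 or 14 days later. Each combination of transplant and day had 1 library. The number of mice behind a library was not given in the sources used here.

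The deposited files held counts of unique molecular identifiers (UMIs) per gene and cell barcode, as the authors obtained them and with no normalization. Per the submitters' processing notes, these came from Cell Ranger 8.0.0 with the mm10 mouse probe set, and R 4.3.3 with Seurat 5 was used afterwards. Per the labels' protocols, fixed cells were processed singly with the 10x Genomics Flex kit, aiming at up to 10000 cells per condition. The files were the filtered matrices of that pipeline, so the separation of cells from empty droplets was made by the authors. Probes read a short part of each transcript, so isoforms were not resolved, and probes could be shared within the Gbp and H2 families. Values of single members of those families were treated as uncertain.

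The labels disagree on the sort. The protocol names cells negative for Cd45 and positive for Cd11b and Cd31. The cell type label of the allogeneic day 4 library gives Cd11b as negative, and the labels of the other 3 libraries name a selection on cKit. The molecule is given as nuclear RNA although whole fixed cells are described. These conflicts could not be settled from the counts, and Kit is reported with the results.

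The 4 libraries held 41768 barcodes, 107898769 UMIs and the same 19059 genes, of which 19048 were matched by identifier to GENCODE vM21 (mm10). The 6 symbols carried by more than 1 gene were kept apart by identifier. Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which left out 7 in the allogeneic day 4, 21 in the syngeneic day 4, 66 in the allogeneic day 14 and 601 in the syngeneic day 14 library. Doublets were scored per library with Scrublet as provided in scanpy 1.11.5. Its automatic threshold called 1, 0, 2 and 1 cells in that order and was taken not to have worked. The cells with the highest scores were removed instead, at 0.8% per 1000 cells, which took out 1118, 1339, 303 and 827 cells and left 37486.

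Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes were chosen without any gene of the response lists, with the aim that clusters depend less on the response compared later. Interferon-induced genes outside the lists, such as Ubd, were not held back. Cluster 1 was led by Calhm6, Nlrc5 and Gbp4 among others and cluster 6 by Ubd and Gbp2b among others, so clusters could still follow the response in part. The first 30 principal components, 15 nearest neighbours with shared-neighbour weights, and Leiden clustering at resolution 1.0 gave 25 clusters. Libraries were not integrated, since library and group were the same thing. Clusters were named from 19 marker lists of endothelial, hepatic and blood cell types, with at least 3 detected markers and the 10 leading genes as a check. The exact naming thresholds and 1 further list, of exocrine pancreas enzymes, were set after the clusters had been seen. Clusters left unnamed by those thresholds held 32.3% of the cells of the allogeneic day 4 library, 12.0% of the syngeneic day 4, 1.97% of the allogeneic day 14 and 12.8% of the syngeneic day 14 library. They were left out, and an alternative included them. The 12 clusters named as endothelial held 29583 cells.

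UMIs were summed over the endothelial-like cells of each library and divided by their total and are given as CPM, the standard library-size scaled count. Cells are not replicates, and with 1 library per group there was no test, and no p-value or standard error is given. A CPM has an exact Poisson 95% interval, a ratio of 2 CPM values an exact conditional 95% interval, and a share of cells an exact Clopper-Pearson 95% interval. These intervals cover counting error alone and say nothing on the spread between animals. Where a library had 0 UMIs of a gene, 3 UMIs served as the floor of that library, and the fold over that floor is given.

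The comparisons were allogeneic against syngeneic at day 4 and at day 14, the difference between those 2 ratios, and day 14 against day 4 within each transplant. A count of genes took those with at least 20 CPM in 1 or both libraries that differed at least 2-fold after 1 CPM was added to each value. Genes were named by rule. For each allogeneic comparison these were the 8 highest and 8 lowest log2 ratios among genes at or above 20 CPM and outside the marker lists of other cell types, and a fixed set of 19 genes around interferon gamma, antigen presentation, adhesion, Kit and Pecam1. The 2 members with the largest log2 ratio in either direction were added for each response list described by its members. For each comparison of days the 5 highest and 5 lowest genes were named. Genes named outside this rule are said to have been chosen after their values were seen.

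The 21 response lists covered the interferon gamma response, the type I interferon response, MHC class I presentation, MHC class II presentation, T cell costimulatory and inhibitory ligands, chemokines, leukocyte adhesion, the NF-kB and TNF response, JAK-STAT receptors and regulators, interferon regulatory factors, cell cycle, the p53 and DNA damage response, cell death, LSEC identity and scavenging, capillarization and basement membrane, angiocrine and Wnt factors, angiogenesis with VEGF and Notch, coagulation and vascular tone, glycolysis and hypoxia, oxidative phosphorylation, and immediate early and heat shock genes. LSEC stands for liver sinusoidal endothelial cell. Of each list, members with a mean of at least 5 CPM were measured, those at least 1.5-fold higher or lower were counted, and the median log2 ratio was taken with 1 CPM added. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries and is no test. Some list symbols were not among the measured genes, among them Cxcl11, Mx1, Mx2, Psme2, Nos3 and Notch4. Fam26f was missed because the data carry it under the newer symbol Calhm6. It was therefore neither counted in the interferon gamma list nor held back from the clustering.

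The comparisons, lists, markers, the rule for named genes, the filters and 18 alternatives were fixed before the data were examined. Added afterwards were 2 alternatives, the choice of sub-populations to compare, the choice of 5 lists given by their summary alone, and the choice of which values are the main results. Of the named genes, 2 are not reported here. The 18 fixed beforehand changed the scaling, the pseudocount, the minimum expression, the cell filter, the doublet removal, the clustering resolution, the cells taken as endothelial, the weight of cells and clusters, and the depth of each cell.

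The steps from summed counts to ratios and lists were tested on simulated counts, with 200 genes changed by known factors. The counts were drawn with Poisson error alone from 1 mean profile pooled over all barcodes of the 4 libraries, at each library's size. They therefore cover counting error only, and not false 2-fold calls from differences between libraries or in the mix of cells. In the day 4 comparison, 7647 genes were in that step, and 50 of 50 genes raised 3-fold and 50 of 50 lowered 3-fold passed the 2-fold mark. In the day 14 comparison, with 7690 genes, 50 of 50 raised and 49 of 50 lowered genes passed. At both days, 0 of 50 genes changed 1.5-fold in either direction passed, and of the genes left as they were 0 of 7447 passed at day 4 and 0 of 7491 at day 14.

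Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. The factors of the trimmed mean of M values (TMM) came from edgeR 4.0.16, in an alternative scaling of the counts.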

Results

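Endothelial cells line the blood vessels of the liver and are among the first recipient cells that donor T cells meet after an allogeneic transplant. The study asked how these cells respond in acute graft-versus-host disease, with interferon gamma and the transcription factor IRF1 at its centre. Transcripts were counted in single cells sorted from the liver of mice given a syngeneic transplant, which carries the effects of conditioning without alloreactivity, or an allogeneic one. Each of the 4 groups (allogeneic and syngeneic, day 4 and day 14) had 1 library, so the differences reported here have no replicate check and the intervals cover counting error alone.

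The libraries held 26733456 UMIs in 11828 barcodes (allogeneic day 4), 51065727 in 12958 (syngeneic day 4), 16114918 in 6216 (allogeneic day 14) and 13984668 in 10766 (syngeneic day 14). Endothelial-like cells numbered 7110, 9784, 4696 and 7993 in that order, with a median of 1750, 3249, 2316.5 and 1033 UMIs. The syngeneic day 14 library was the shallowest per cell, and the median mitochondrial share of its endothelial-like cells was 3.87%, against 1.47% in the allogeneic day 4, 1.43% in the syngeneic day 4 and 0.585% in the allogeneic day 14 library. The mitochondrial transcript mt-Co1, chosen after its values were seen, stood at 5244 CPM there against 2092, 1998 and 1439 CPM.

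Liver sinusoidal endothelial cell (LSEC)-like clusters, with scavenger receptors such as Stab2 and Clec4g, made up 51.9% (95% interval 50.9 to 52.8) of the kept cells of the allogeneic day 4 library and 67.7% (66.9 to 68.6) of the syngeneic day 4 library. At day 14 they made up 55.4% (54.1 to 56.7) and 64.4% (63.4 to 65.3). Large-vessel-like clusters held 13.3%, 15.3%, 20.5% and 20.6% of cells in the order used above, and a lymphatic-like cluster with Ccl21a, Mmrn1 and Pdpn held 1.31%, 1.37%, 4.395% and 0.643%. The LSEC-like class included cluster 16 (248 cells of the allogeneic day 4 library), which was led by histone genes and had LSEC markers below the other cells (mean log2 fold -0.71). Cluster 1, 86.4% of the allogeneic day 4 LSEC-like cells, was slightly below them too (-0.099). Cluster 0, 90.15% of the syngeneic day 14 LSEC-like cells, had mitochondrial transcripts among its leading genes. The large-vessel-like class was made of different clusters at day 14. Cluster 4, led by Nuak1 and Rspo3 among others, held 1678 of its 1923 syngeneic and 50 of its 1198 allogeneic cells, and its pericentral LSEC markers (mean log2 fold 0.88) were above its large-vessel markers (0.40). Cluster 12 held 726 allogeneic and 46 syngeneic cells. These shares are set in part by the sort, whose labels differ between libraries, and by the clusters left unnamed. Pecam1 (ENSMUSG00000020717), which encodes the sorting antigen CD31, was at 826 against 1002 CPM at day 4 and 1353 against 1176 CPM at day 14, allogeneic first. Kit (ENSMUSG00000005672), the receptor named in 3 of the cell type labels, was at 361 against 401 and at 534 against 459 CPM.

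At day 4 after transplant, endothelial-like cells of the allogeneic library stood apart from those of the syngeneic library by a broad interferon gamma programme. Of 29 measured genes of the interferon gamma response, 26 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 2.20. For 5 genes of MHC class II presentation, which shows peptides to CD4 T cells, the allogeneic level was 37.5 to 88.4 times the syngeneic one. Among genes of LSEC identity, 13 of 25 were lower, and in the p53 response 14 of 25. Of 7722 genes compared, 190 were at least 2-fold higher and 139 at least 2-fold lower in the allogeneic library, with no test possible.

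The highest ratio belonged to Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418, mm10), the master regulator of MHC class II transcription, at 85.5 against 0.968 CPM (ratio 88.4, 95% interval 63.2 to 127). Its targets followed. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the invariant chain, was at 268 against 5.89 CPM (ratio 45.5, 39.7 to 52.5). H2-Eb1 (ENSMUSG00000060586) was 46.1 times, H2-Aa (ENSMUSG00000036594) 42.6 times and H2-Ab1 (ENSMUSG00000073421) 37.5 times as abundant, at 129, 69.5 and 172 CPM in the allogeneic library. These 3 genes lie together on chromosome 17 between 34257689 and 34316674 and encode chains of the class II molecules, a family whose members may share probes. In the MHC class II list, 8 of 13 measured members were higher and 1 lower, with a median log2 ratio of 2.05. That median depended on which low genes were measured, from 0.62 with no minimum expression to 4.74 with a higher one, and was 1.30 with the unnamed clusters included. Kupffer cells and dendritic cells also express these genes. The summed marker level of Kupffer cells and macrophages in the same cells was lower in the allogeneic library (894 against 1829 CPM, mostly Apoe), and that of dendritic cells was higher (2171 against 1250 CPM, mostly Bst2, itself an interferon-induced gene).

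Genes that act downstream of interferon gamma followed the same direction. Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes the inhibitory ligand PD-L1, was at 617 against 54.1 CPM (ratio 11.4, 10.9 to 11.998). The guanylate binding proteins Gbp2b, Gbp8 and Gbp2, antimicrobial GTPases of 1 family, were 61.3, 16.8 and 7.26 times as abundant, with the reserve that family members may share probes. Zbp1, a sensor of Z-form nucleic acids, was at 364 against 23.6 CPM (ratio 15.4). Ido1, which degrades tryptophan, had 20 UMIs against 1 (ratio 49.5, 7.92 to 2051).

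Irf1 itself (ENSMUSG00000018899, chromosome 11, 53770014 to 53778374) differed less than its usual targets. It was abundant in both libraries, at 2020.1 CPM (1997 to 2043) in the allogeneic and 1503 CPM (1490 to 1515) in the syngeneic library (ratio 1.34, 1.33 to 1.36). Within the interferon regulatory factors, Irf7 (486 against 261 CPM) and Irf8 (439 against 257 CPM) had the largest ratios, and 3 of 9 measured members were higher and 0 lower (median log2 ratio 0.43). The receptor chains Ifngr1 (47.7 against 57.4 CPM) and Ifngr2 (41.0 against 53.3 CPM) were slightly lower in the allogeneic library. Of the 23 measured JAK-STAT receptors and regulators, 7 were higher and 0 lower (median 0.03), among them Socs2, a feedback inhibitor of cytokine signalling, at 147 against 66.4 CPM. The type I interferon list had 16 of 34 members higher and 1 lower (median 0.53), with Oas2, an antiviral nucleotide synthetase, at 24.1 against 4.81 CPM.

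Classical antigen presentation was higher as well. Of 20 measured genes of MHC class I presentation, 16 were higher and 0 lower (median log2 ratio 1.20). The immunoproteasome subunit Psmb9 was at 255 against 59.0 CPM and the peptide transporter Tap1 at 867 against 254 CPM, and the ends of these neighbouring genes overlap on opposite strands. H2-K1 was at 2089 against 1211 CPM and B2m at 906 against 549 CPM. Of 17 measured costimulatory and inhibitory ligands, 7 were higher and 2 lower (median 0.30), with Il18bp, a soluble antagonist of interleukin 18, at 283 against 56.7 CPM. For chemokines, 6 of 12 members were higher and 0 lower (median 0.57). The T cell attractants Cxcl9 (1023 against 195 CPM, ratio 5.26) and Cxcl10 (1666 against 900.0 CPM, ratio 1.85) and the membrane-bound Cx3cl1 (17.2 against 2.63 CPM) were among them.

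Leukocyte adhesion genes showed no common direction, with 3 of 16 higher and 0 lower (median log2 ratio 0.10). Vcam1, which binds integrins of leukocytes, was at 1055 against 612 CPM and Itgb3 at 97.7 against 19.0 CPM, whereas Icam1 was lower in the allogeneic library (966 against 1176 CPM, ratio 0.821). The NF-kB and TNF response had 8 of 24 members higher and 0 lower (median 0.32), but 4 of 23 higher and 4 lower within LSEC-like cells (median 0.03). Of 23 cell death genes, 6 were higher and 1 lower (median 0.05), with the pyroptosis effector Gsdmd at 266 against 102 CPM and Casp12 at 44.1 against 20.02 CPM. Of 22 coagulation and vascular tone genes, 5 were higher and 3 lower (median 0.20). Ptgs2, the inducible cyclooxygenase, was at 12.8 against 0.581 CPM (ratio 22.035, 14.0 to 36.4).

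The lower side held markers of differentiated sinusoidal endothelium. Of 25 LSEC identity and scavenging genes, 13 were at least 1.5-fold lower and 1 higher in the allogeneic library (median log2 ratio -0.62), a median below those of all 10000 matched random lists. Aass, an enzyme of lysine breakdown used as an LSEC marker, was at 5.20 against 39.2 CPM (7.52-fold lower) and Oit3 at 179 against 505 CPM. The p53 and DNA damage response had 14 of 25 members lower and 0 higher (median -0.59), also below all random lists. Gtse1 was at 66.7 against 159 CPM and the repair factor Xpc at 21.7 against 52.4 CPM. The median of this list was -0.60 within LSEC-like cells and smaller in size in clusters 9, 10 and 14 (-0.27, -0.44 and -0.34). The lowest ratios outside these lists belonged to Itga8 (1.51 against 20.2 CPM, 13.5-fold lower), the cytokine receptor Cntfr (3.97 against 35.1 CPM) and Tiam1, an activator of the GTPase Rac (5.82 against 43.7 CPM). Plxdc1, Ntf3, Btnl9 and Il16 were 4.12-fold to 4.81-fold lower. Oit3, Tiam1, Plxdc1, Btnl9 and Il16 also led LSEC-like clusters drawn mostly from the syngeneic libraries, so the size of their difference is tied to the mix of clusters. They stayed lower in the allogeneic library with shared clusters given the same weight, and in the LSEC-like clusters alone.

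The remaining lists had medians between -0.30 and 0.13. Capillarization and basement membrane genes had 4 of 24 members higher and 4 lower (median log2 ratio -0.03) and leaned lower within each part compared, from -0.21 in cluster 9 to -0.35 in cluster 10, with 1 of 22 higher and 6 lower in LSEC-like cells (-0.30). Among them were Ly6a at 811 against 259 CPM and the collagen crosslinker Loxl2 at 6.09 against 21.5 CPM. Angiocrine and Wnt factors had 2 of 16 higher and 5 lower (median -0.14), with Pdgfb, a mitogen for pericytes, at 98.1 against 46.1 CPM and Bmp4 at 30.7 against 81.7 CPM. Of 27 genes of angiogenesis, 5 were higher and 4 lower (median 0.06), and the VEGF receptors Nrp1 (196 against 498 CPM) and Kdr (445 against 887 CPM) were among the lower ones. Oxidative phosphorylation had 0 of 32 members higher and 3 lower (median -0.30, below the random range, which ended at -0.20, and in cluster 10 0 of 30 higher and 15 lower with a median of -0.56), glycolysis and hypoxia 3 of 19 higher and 3 lower (median 0.13), cell cycle 0 of 13 higher and 2 lower (median -0.17), and immediate early and heat shock genes 2 of 26 higher and 1 lower (median 0.00). Summed hepatocyte markers were alike in the 2 libraries (1590 against 1714 CPM). The clusters left unnamed, 32.3% of the allogeneic and 12.03% of the syngeneic cells, are outside all of these values, and with them the Irf1 log2 ratio was 0.63 in place of 0.43. It was 1.10 when the clusters shared by all 4 libraries were given the same weight.

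**Figure D1:**
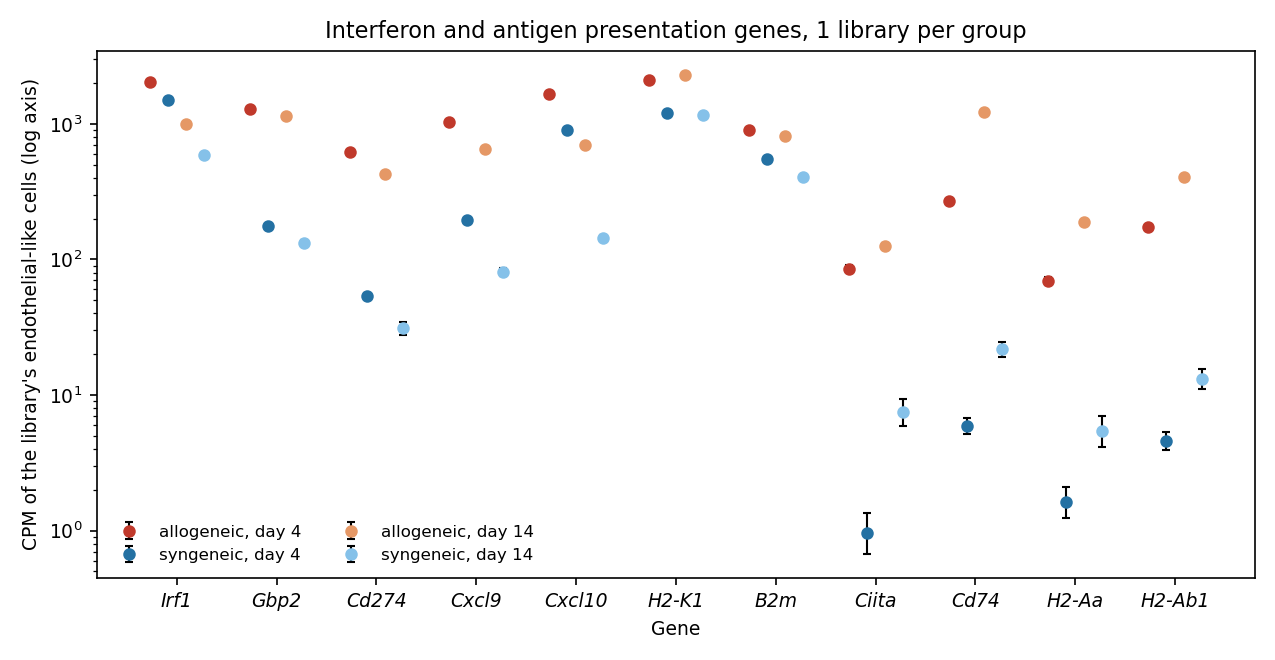
CPM on a log axis of 11 interferon and antigen presentation genes in the summed endothelial-like cells of each of the 4 libraries, with 1 point per library and bars for the 95% counting interval. Irf1 lies between 588 and 2020.1 CPM in the 4 libraries, while Ciita spans 0.968 to 126 CPM and Cd74 5.89 to 1215 CPM, both higher in the allogeneic library of each day.

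At day 14, the allogeneic library again showed the interferon gamma programme, with 28 of 29 measured genes higher, 0 lower and a median log2 ratio of 2.28. MHC class II transcripts reached a higher level than at day 4 in the allogeneic library, with Cd74 at 1215 CPM. In the type I interferon list 29 of 34 genes were higher, and in the chemokine list 8 of 13. The collagens Col14a1 and Col6a3 and the Rac activator Tiam1 had the lowest ratios. Of 8262 genes compared, 317 were at least 2-fold higher and 167 lower in the allogeneic library. The syngeneic library of this day was the shallow one with the high mitochondrial share given above.

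The highest ratio was that of Ubd (ENSMUSG00000035186, chromosome 17, 37193892 to 37196095), a ubiquitin-like modifier induced by interferon gamma and TNF, at 90.8 CPM against 0.382 CPM from 4 UMIs (ratio 238, 92.7 to 874). Steap2 (ENSMUSG00000015653, chromosome 5, 5664829 to 5694578), a metalloreductase, followed at 105 against 0.764 CPM (ratio 138, 69.6 to 319), and its neighbour Cfap69 (ENSMUSG00000040473, 5579278 to 5664239) at 251 against 4.39 CPM (ratio 57.2, 42.8 to 78.2). Thbs1 (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), thrombospondin 1, an inhibitor of angiogenesis and activator of latent TGF-beta, was at 569 against 10.8 CPM (ratio 52.7, 43.8 to 64.0). Each of these 4 genes led a cluster drawn mostly from the allogeneic day 14 library, which ties their level to the mix of clusters.

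Of 13 MHC class II genes measured, 9 were higher and 0 lower (median log2 ratio 2.98). The MHC class II presentation median was 1.38 with no minimum expression, 2.29 in the LSEC-like clusters alone and 3.66 with a gate on endothelial markers per cell. Cd74 was at 1215 against 21.8 CPM (ratio 55.8, 49.0 to 63.9), H2-Eb1 at 409 against 11.2 CPM, H2-Ab1 at 408 against 13.2 CPM, H2-Aa at 187 against 5.44 CPM and Ciita at 126 against 7.45 CPM (ratio 16.95, 13.5 to 21.6). Kupffer-like cells, which also carry these transcripts, made up 12.7% (11.9 to 13.6) of the allogeneic library and 0.268% (0.173 to 0.395) of the syngeneic one. Of the 743 such allogeneic cells, the 191 of cluster 17 had Cd74 at 15609 CPM. The 552 of cluster 15, which also held LSEC transcripts, had it at 2040 CPM. Inside the endothelial-like cells the summed Kupffer cell markers were lower in the allogeneic library (1034 against 1887 CPM, mostly Apoe), while the Kupffer cell genes Cd5l (81.7 against 15.2 CPM) and C1qb (70.3 against 8.02 CPM) were higher.

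Cd274 was at 428 against 31.2 CPM (ratio 13.7, 12.3 to 15.4), Gbp2 at 1138 against 132 CPM and Gbp2b at 145 against 2.67 CPM. Ido1 had 79 UMIs (6.03 CPM) against 0, 21.05-fold over a floor of 3 UMIs in that library, with 16.7 as the lower end of the exact interval of the ratio. Irf1 was at 990.1 CPM (973 to 1007) against 588 CPM (574 to 603), a ratio of 1.68 (1.63 to 1.74). Set against the deeper syngeneic day 4 library, a control chosen after the data were seen, the Irf1 log2 ratio turned to -0.60, those of Cxcl10, Vcam1 and Socs1 to -0.37, -0.31 and -0.38, those of Casp4 and Inhbb to -0.94 and -0.17, and that of Irf8 to -0.003. The median of the type I interferon list turned to -0.05. That control also carries the difference between the days, given further on. Irf8 (256 against 54.1 CPM) and Irf7 (272 against 111 CPM) led the interferon regulatory factors, of which 3 of 9 were higher and 0 lower (median 0.41). Of 22 JAK-STAT receptors and regulators, 9 were higher and 0 lower (median 0.40), with the feedback inhibitor Socs1 at 144 against 56.3 CPM. Ifngr1 was at 71.2 against 54.9 CPM and Ifngr2 at 56.2 against 57.4 CPM, the latter ratio not separable from 1 at this depth (0.980, 0.879 to 1.09). The type I interferon list had 0 members lower and a median of 0.92, with Zbp1 at 343 against 17.5 CPM and Oas2 at 18.01 against 1.62 CPM.

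MHC class I presentation had 16 of 20 members higher and 0 lower (median log2 ratio 1.07), with Tap1 at 655 against 170 CPM, H2-Q7 at 638 against 197 CPM, H2-K1 at 2275 against 1161 CPM and B2m at 814 against 408 CPM. Of 17 costimulatory and inhibitory ligands, 11 were higher and 1 lower (median 0.69), among them Fgl2, a prothrombinase with a soluble immunosuppressive form, at 358 against 68.4 CPM. The chemokine list had 0 members lower and a median of 2.04. It was smaller within single classes, at 0.72 in LSEC-like cells (5 of 10 higher, 0 lower), 0.77 in cluster 10 (7 of 11 higher, 3 lower) and 1.55 in cluster 14 (11 of 15 higher, 2 lower). With shared clusters given the same weight it was 0.65. Cxcl9 was at 655 against 81.3 CPM, Cxcl10 at 698 against 143 CPM and Ccl21a, which lymphatic endothelium secretes to attract T cells and dendritic cells, at 525 against 80.0 CPM. Ccl21a was concentrated in the lymphatic-like cluster, where it was at 7386 against 5850 CPM (ratio 1.26, 1.17 to 1.36), and that cluster held 4.395% of the allogeneic and 0.643% of the syngeneic cells. Fgl2 was also among the leading genes of that cluster, so the size of its difference is tied to the mix of clusters too.

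Adhesion genes went both ways, with 4 of 16 higher and 2 lower (median log2 ratio 0.04). Itgb3, an integrin chain of endothelium and platelets, was at 167 against 12.1 CPM, Vcam1 at 495 against 314 CPM, and Alcam, a ligand of CD6 on T cells, at 21.5 against 99.1 CPM. With shared clusters given the same weight the Alcam log2 ratio turned to 1.13. Icam1 showed no difference beyond counting error (512 against 525 CPM, ratio 0.974, 0.940 to 1.01). The NF-kB and TNF response had 9 of 23 members higher and 0 lower (median 0.44), and its median turned to -0.32 with the syngeneic day 4 control. Of 23 cell death genes 7 were higher and 1 lower (median 0.43), with Casp12 at 90.2 against 26.0 CPM and the inflammatory caspase Casp4 at 318 against 160.1 CPM. The p53 list had 3 of 26 higher and 0 lower (median 0.09, and -0.35 with that control). Its largest ratios were those of the apoptosis gene Pmaip1 (11.1 against 2.10 CPM) and the death receptor Tnfrsf10b (131 against 65.1 CPM), whose log2 ratios turned to -1.17 and -0.65 with shared clusters given the same weight. That weighting rests in part on 57 cells of cluster 1 and 60 of cluster 14 in the syngeneic library. Pmaip1 had 22 UMIs in all endothelial-like cells of that library.

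Genes of matrix and vessel growth differed by list. Of 26 capillarization and basement membrane genes, 10 were higher and 3 lower (median log2 ratio 0.46), above all 10000 random lists. Within LSEC-like cells 3 of 20 were higher and 3 lower (median 0.12). Col15a1, a collagen of basement membranes, was at 24.8 against 1.15 CPM (ratio 21.7, 12.2 to 42.3) and the laminin chain Lamb1 at 32.1 against 2.86 CPM. The angiogenesis list had 6 of 27 higher and 4 lower (median 0.07) but medians below 0 in LSEC-like cells (-0.17), cluster 10 (-0.28) and cluster 14 (-0.295), with the tip cell genes Esm1 at 49.8 against 3.53 CPM and Apln at 47.9 against 8.21 CPM. Of 17 angiocrine and Wnt factors, 6 were higher and 5 lower (median 0.15), against 8 of 16 and 1 in LSEC-like cells (0.66) and 6 of 16 and 0 in cluster 10 (0.38), with Angpt2, a destabilizer of vessels, at 102 against 20.2 CPM and the activin subunit Inhbb at 478 against 107 CPM. Coagulation and vascular tone had 7 of 22 higher and 3 lower (median 0.08), including the plasminogen activator Plat (59.1 against 12.03 CPM) and Serpine2 (21.4 against 4.01 CPM, log2 ratio -0.10 with shared clusters given the same weight).

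LSEC identity genes were split, with 8 of 25 lower and 2 higher (median log2 ratio -0.18). Aass was at 12.4 against 37.8 CPM and Ehd3, a membrane-shaping protein, at 758 against 2042 CPM. The lowest ratios belonged to Col14a1 (1.07 against 25.8 CPM, 24.4-fold lower), Tiam1 (5.42 against 76.9 CPM), Col6a3 (9.24 against 122 CPM), the neurofilament gene Nefh (2.21 against 28.2 CPM), Insyn2a (3.43 against 34.9 CPM) and Rnf43, a ubiquitin ligase that removes Wnt receptors (2.29 against 22.9 CPM). Col6a3 led cluster 4, which had 1678 cells in the syngeneic and 50 in the allogeneic library, so its level is tied to the mix of clusters. Within the LSEC-like clusters alone the log2 ratio of Rnf43 was 0.06. The neurotrophin Ntf3 and Cntfr were 6.58-fold and 6.33-fold lower, the same direction as at day 4. Cell cycle genes had 5 of 19 higher and 2 lower (median 0.27), glycolysis and hypoxia 6 of 20 higher and 0 lower (median 0.21), oxidative phosphorylation 2 of 32 higher and 0 lower (median 0.09), and immediate early and heat shock genes 4 of 25 higher and 3 lower (median 0.09, but -0.87 with the syngeneic day 4 control and -0.62 with shared clusters given the same weight). Within classes the last list was lower, with 0 of 25 higher and 19 lower in cluster 10 (median -0.94) and 2 of 22 higher and 6 lower in LSEC-like cells (median -0.25). Summed markers of erythroid cells (93.3 against 28.0 CPM) and exocrine pancreas (55.0 against 21.2 CPM) inside these cells were higher in the allogeneic library, and those of hepatocytes lower (163 against 457 CPM).

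**Figure D2:**
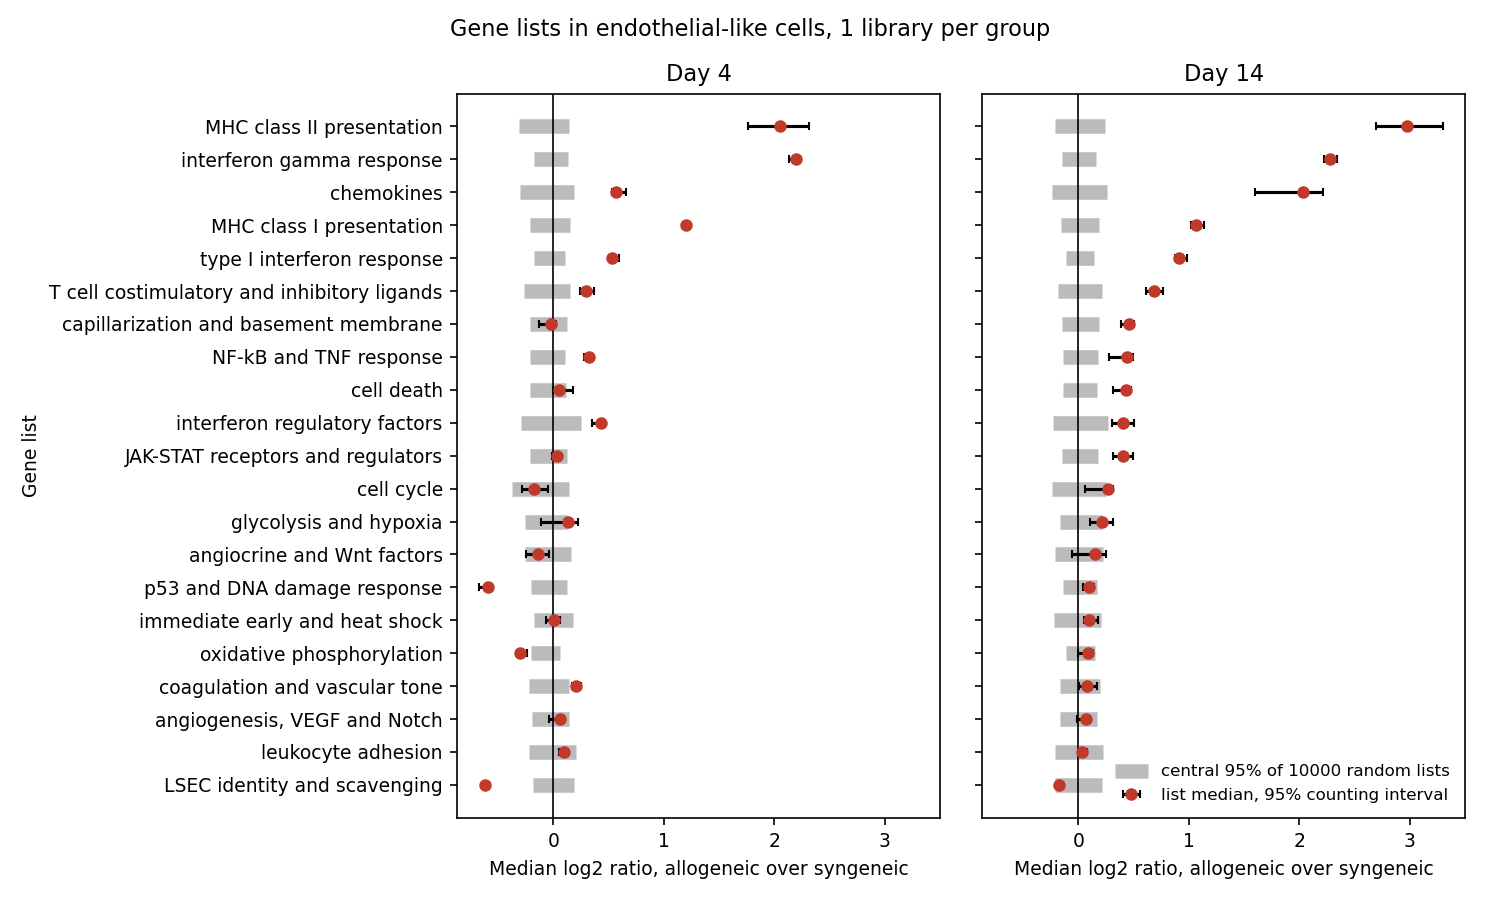
Median log2 ratio, allogeneic over syngeneic, of each of the 21 gene lists at day 4 and day 14 in endothelial-like cells (points, with 95% counting intervals), over the central 95% of 10000 matched random lists (grey bars). The interferon gamma response lies at 2.20 and 2.28, and the p53 list lies at -0.59 at day 4 and 0.09 at day 14.

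The ratios of the 2 days were then set side by side, to ask which part of the allogeneic difference belonged to which day. This difference could not be tested with 1 library per group. The interferon gamma response differed little between the days (day 14 minus day 4 of the median log2 ratio, 0.08) and so did MHC class I presentation (-0.13). Chemokines had the largest gap towards day 14 (1.47), with Cxcl10 going from a ratio of 1.85 to 4.88, followed by MHC class II (0.93) and the p53 list (0.68). The chemokine gap turned to -0.15 when shared clusters were given the same weight, and the MHC class II gap to -1.94 when low genes were left out. Thbs1 had a ratio of 3.31 at day 4 (77.5 against 23.4 CPM) and 52.7 at day 14. Ubd was already at 17.8 against 0.221 CPM at day 4, and Steap2 at 48.9 against 4.07 CPM. The Ciita ratio was lower at day 14, when its level was higher in both libraries. Tnfrsf10b was lower in the allogeneic library at day 4 (75.8 against 129 CPM) and higher at day 14.

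Between day 4 and day 14, the immediate early and heat shock, interferon, NF-kB and chemokine lists were lower at the later day after either transplant. Each day was a separate library, so handling that differed between libraries cannot be told apart from the day. The median gene was higher at day 14 by a log2 ratio of 0.23 in the allogeneic and 0.19 in the syngeneic pair, so list and gene values here are given relative to that shift. Relative to it, immediate early and heat shock genes lay at -1.12 in the allogeneic and -1.26 in the syngeneic pair, type I interferon genes at -0.88 and -1.31, the NF-kB and TNF response at -0.65 and -0.75, the interferon gamma response at -0.60 and -1.01, and chemokines at -0.50 and -0.76. MHC class II presentation went the other way, at 1.04 with 8 of 13 members higher in the allogeneic pair and 0.37 with 3 of 8 higher in the syngeneic pair. Between the allogeneic days the share of Kupffer-like cells went from 0.187% to 12.7%. That of the lymphatic-like cluster, with the highest Cd74 of the parts compared, went from 1.31% to 4.395%. Cluster 12, which was not among those parts, went from 129 to 726 cells and had a higher Cd74 still, at 4026 CPM at day 14. It held 8044 of the 15915 endothelial Cd74 UMIs of the allogeneic day 14 library. Kupffer-like cells themselves are outside these sums, but the mix of cells differed between the days. Capillarization and basement membrane genes lay at 0.44 in the allogeneic pair (9 of 25 higher, 3 lower) and -0.14 in the syngeneic pair (2 of 24 higher, 8 lower). The p53 list lay at -0.15 and -0.61. With shared clusters given the same weight, and without the shift taken off, the syngeneic medians came closer to 0, from -1.07 to -0.11 for immediate early and heat shock genes, from -0.82 to -0.22 for the interferon gamma response and from -1.12 to -0.52 for type I interferon genes.

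In the allogeneic pair, the highest genes at day 14 relative to the shift were the renin gene Ren1 (26.9 against 1.23 CPM, 18.5-fold), the matrix protein Sparcl1 (112 against 9.44 CPM), Col15a1 (24.8 against 2.19 CPM), Ccdc85a and Thbs1 (569 against 77.5 CPM). The lowest included Adamts4, a protease of matrix proteoglycans (87.2 against 518 CPM, 7.001-fold lower), and Pzp, Mat1a, Plg and Gc, which are hepatocyte transcripts and went with a lower sum of hepatocyte markers (163 against 1590 CPM). In the syngeneic pair, Gbp8 (36.3 against 8.08 CPM), the kinase Nuak1 (566 against 149 CPM), Prr15, Cd74 (21.8 against 5.89 CPM) and Dnm3 were highest. The interferon-induced Ifit1 (16.1 against 168 CPM, 11.9-fold lower), the urokinase receptor Plaur (33.1 against 276 CPM), Ifi202b, Pzp and Plg were lowest, with summed hepatocyte markers at 457 against 1714 CPM. Ren1 led cluster 6 and Sparcl1, Ccdc85a and Thbs1 led cluster 12, both drawn mostly from the allogeneic day 14 library. Nuak1 led cluster 4, with 926 syngeneic cells at day 4 and 1678 at day 14. Adamts4, Plaur and Ifit1 led cluster 2, drawn mostly from the syngeneic day 4 library. The size of these differences is thus tied to the mix of clusters, although Thbs1 also differed within allogeneic cluster 12 (2897 against 1267 CPM).

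Counts of genes at least 2-fold apart between the days depended on scaling, on the expression minimum and, in the allogeneic pair, on the choice of cells. Those of the syngeneic pair also moved with the weight of cells and clusters, as given further on. By CPM, 281 of 8095 genes were higher and 173 lower at day 14 in the allogeneic pair, which became 142 and 306 relative to the shift, 148 and 286 with median of ratios scaling, and 137 and 305 with TMM. They were 508 and 314 with no cell filter, 466 and 290.0 with 2 times as many doublets removed, 502 and 281 at the coarser clustering and 551 and 327 with a gate on endothelial markers per cell. With the unnamed clusters included, a choice made after the data were seen, they were 522 and 325. With no minimum expression they were 794 and 435. In the syngeneic pair, 121 of 8073 were higher and 305 lower by CPM, 59 and 448 relative to the shift, 73 and 409 with median of ratios scaling, 51 and 481 with TMM, and 246 and 474 with no minimum expression.

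The allogeneic difference was also looked at within parts of the endothelium, to see whether it held inside single cell classes. The interferon gamma response was higher in each part compared. Its median log2 ratio was 2.13 at day 4 and 2.39 at day 14 in LSEC-like cells, 1.95 at day 4 in the large-vessel-like cluster 9, led by Selp and Sele, 1.88 and 2.03 in the large-vessel-like cluster 10, led by Gja5 and Mgp, and 2.40 and 3.50 in the lymphatic-like cluster 14. Cd274 was 10.5 times as abundant in the allogeneic LSEC-like cells at day 4 (624 against 59.4 CPM) and 9.83 times at day 14 (348 against 35.4 CPM). Irf1 was less even. At day 4 its ratio was 1.21 in LSEC-like cells, 0.941 (0.908 to 0.975) in cluster 9, 1.48 in cluster 10 and 2.73 (2.46 to 3.04) in cluster 14, and at day 14 it was 1.85, 2.004 and 1.96 in LSEC-like cells, cluster 10 and cluster 14.

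MHC class II transcripts were higher in clusters 9, 10 and 14 than in LSEC-like cells. In the allogeneic library Cd74 was at 45.7 CPM in LSEC-like cells, 504 in cluster 9, 642 in cluster 10 and 1694 in cluster 14 at day 4, against 2.52, 4.59, 5.87 and 151 CPM in the syngeneic library. At day 14 it was at 318, 1725 and 3404 CPM in LSEC-like cells, cluster 10 and cluster 14, against 12.4, 61.8 and 222 CPM. LSEC identity genes had negative medians in these parts at day 4, from -0.46 in LSEC-like cells to -0.95 in cluster 14, but at day 14 were at -0.25 in LSEC-like cells and 0.18 in both cluster 10 and cluster 14. Different clusters made up most of the LSEC-like cells of each library, cluster 1 (86.4%) in the allogeneic and cluster 2 (34.9%) in the syngeneic day 4 library, and cluster 6 (77.7%) and cluster 0 (90.2%) at day 14. Cluster 9 had 18 cells in the syngeneic day 14 library and was not compared at that day. Cluster 12, with 46 cells in that library, was not among the parts compared, and its Cd74 was at 4026 CPM in the allogeneic day 14 library.

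**Figure D3:**
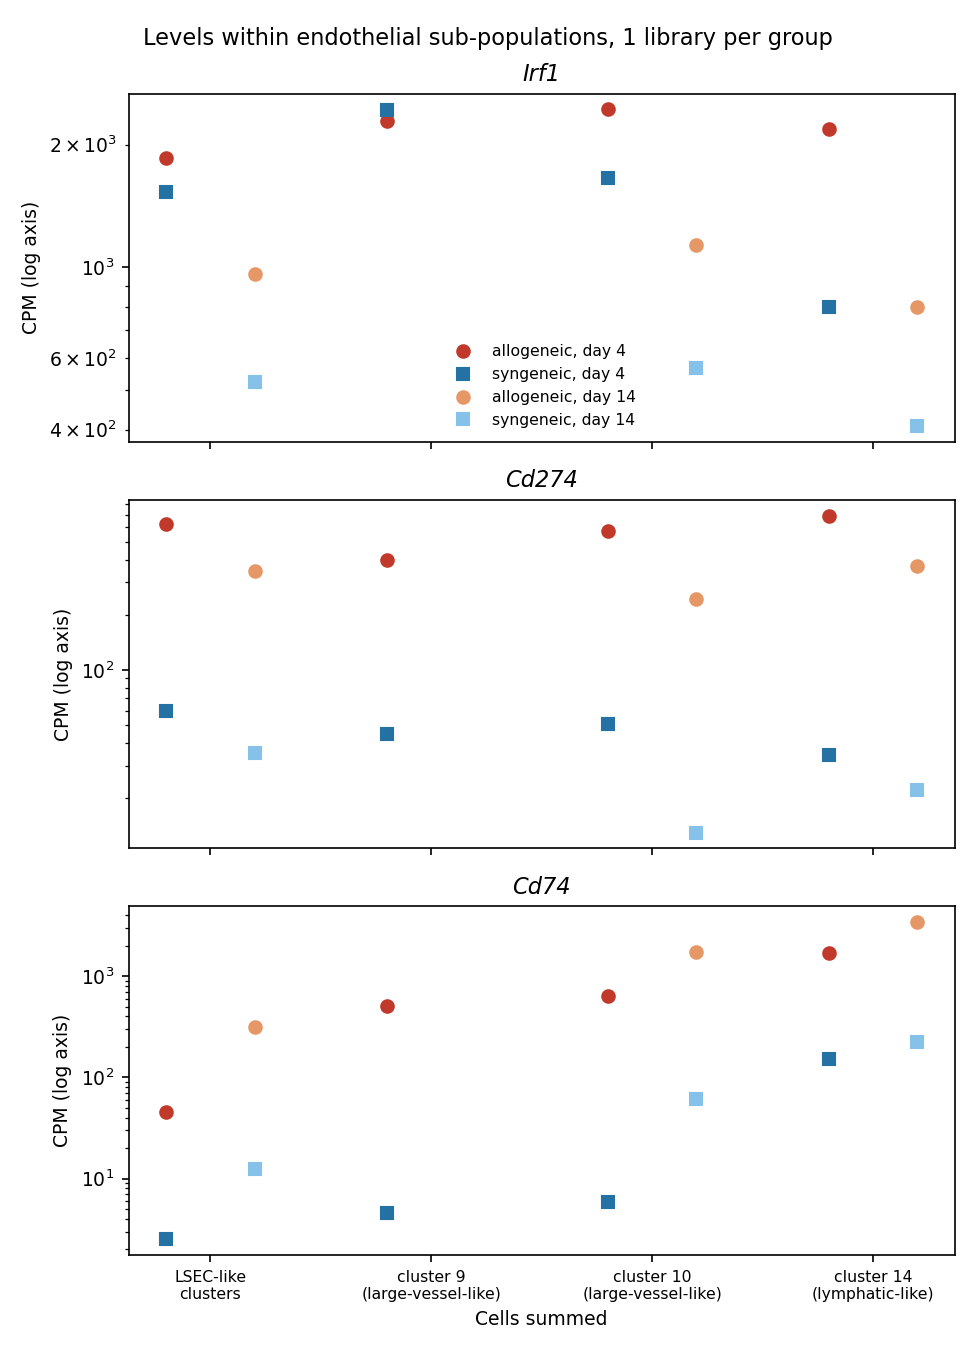
CPM on a log axis of Irf1, Cd274 and Cd74 in the LSEC-like clusters and in clusters 9, 10 and 14, with 1 point per library (circles allogeneic, squares syngeneic) and each panel on its own scale. Cd74 in the allogeneic libraries goes from 45.7 CPM in LSEC-like cells at day 4 to 3404 CPM in cluster 14 at day 14, and Irf1 in cluster 9 is the single case in which the allogeneic point (2283 CPM) lies under the syngeneic one (2426 CPM).

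Further lists differed between the parts compared, or from their value in the summed cells. At day 4, leukocyte adhesion had 2 of 16 members higher and 5 lower in LSEC-like cells (median log2 ratio -0.22), and angiogenesis 2 of 26 higher and 12 lower in cluster 14 (-0.54). Chemokines were at -0.03 in cluster 10 and 1.71 in cluster 14 at that day, coagulation and vascular tone at -0.04 in LSEC-like cells and -0.27 in cluster 14, and glycolysis and hypoxia at -0.17 in LSEC-like cells. At day 14, coagulation and vascular tone had 14 of 21 members higher and 0 lower in cluster 14 (0.78), whereas cell cycle genes had 3 of 20 higher and 9 lower there (-0.38). The p53 list had 0 of 25 higher and 7 lower in cluster 10 (-0.12) and 4 of 26 higher and 8 lower in cluster 14 (-0.25).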

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

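The tests of explanations in this part were chosen after the results were seen, while the thinning of cells and the same weight for clusters that 2 values rest on were fixed before the data.

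Tnfrsf10b was lower in the allogeneic library at day 4 and higher at day 14, a difference of 1.76 between the log2 ratios that was not tested. With shared clusters given the same weight the day 14 log2 ratio turned to -0.65, below 0 as at day 4 without that weighting. This weighted value rests in part on few syngeneic day 14 cells, 57 of cluster 1 and 60 of cluster 14. Cells outside the endothelial comparisons also stood out, although the sort was on Cd45-negative cells and would remove most blood cells. Kupffer cell and macrophage-like cells were 12.7% of the allogeneic day 14 library, against 0.268% of the syngeneic one. In the same library erythroid-like cells were 1.33%, exocrine pancreas-like cells 1.13%, mast cell and basophil-like cells 0.787% and stellate and fibroblast-like cells 0.513%, each above the syngeneic library of that day. Unnamed clusters held 32.3% of the allogeneic day 4 library, against 12.03% of the syngeneic one.

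The Kupffer-like cells of the allogeneic day 14 library were of at least 2 kinds. Cluster 17 (191 cells) had Cd74 at 15609 CPM, Cd5l at 8597 CPM and C1qa at 3102 CPM. Cluster 15 (552 cells) had C1qa at 360 CPM beside the LSEC genes Clec4g at 1381 CPM and Stab2 at 858 CPM, so it held transcripts of both types. Endothelial transcripts were also present in the erythroid-like cluster 18 (Stab2 at 1114 CPM, Cdh5 at 431 CPM) and the exocrine pancreas-like cluster 20 (732 and 238 CPM). In the LSEC-like cluster 6 of that library they were at 1106 and 474 CPM, and Cdh5 in cluster 15 was at 477 CPM. The shares of these classes therefore include cells that also held endothelial transcripts.

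The first pattern weighed was the higher level of MHC class II transcripts in the allogeneic library, since Kupffer-like RNA or doublets could carry them into endothelial cells, so the share of such RNA needed to give Cd74, H2-Aa, H2-Ab1 and H2-Eb1 was set against the share that Cd5l, C1qa, C1qb and C1qc allow. At day 14 the lowest needed share was 5.27 times the highest allowed share in cluster 10 (6.47% for H2-Aa against 1.23% for C1qc) and 10.89 times in cluster 14, which argues against this source in these cells. At day 4 it was 14.05 times in cluster 10 (49.3% for H2-Aa against up to 3.51% for C1qb), with a thin and mixed reference of 20 cells of cluster 15 that held 7 to 16 UMIs of each class II gene, but counting error still left at least 23.4% for H2-Aa, which argues against this source there too. In LSEC-like cells at day 14 the same quotient was 0.96, with H2-Aa needing 1.59% and C1qb allowing up to 1.66%. H2-Eb1, Cd74 and H2-Ab1 needed more (1.97%, 2.04% and 2.27%), but the markers themselves gave shares from 0.821% to 1.52%, a spread wider than that margin, so in LSEC-like cells Kupffer-like RNA cannot be told apart from their own expression.

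The second pattern was the interferon gamma response in the allogeneic libraries. Depth per cell was argued against, since the lower of the medians of the 2 days was 2.14 with every cell thinned to 1000 UMIs. A different mix of endothelial clusters was argued against too, since the lowest median within the LSEC-like clusters and clusters 9, 10 and 14 was 1.88. Animals or handling that differed between libraries cannot be told apart from the transplant, with 1 library per group. An allogeneic response to interferon gamma therefore remains a hypothesis among these open explanations.

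The third pattern was the lead of hepatocyte transcripts in cluster 5, an unnamed cluster with 2481 cells in the allogeneic day 4 library and 144, 11 and 13 in syngeneic day 4, allogeneic day 14 and syngeneic day 14. Hepatocyte RNA, free or from hepatocytes caught with the cells, could give it, as 1 source keeps its genes in 1 ratio. Relative to cluster 1 of that library, Alb was 3.24 times as abundant and the median excess of Fga, Fgb, Fgg and Hp was 0.993 times that of Alb. Such a source would give this, although the test does not part free RNA from doublets. Those genes were taken from the leading genes of cluster 5, so they are no independent check. The excess of the hepatocyte gene Trf, which was not among them, was 1.14 times that of Alb. The endothelial gene Cdh5 was 1.30 times and Cd274 1.49 times as abundant as in cluster 1. Irf1 was at 3099 against 1723 CPM, Cxcl10 at 3126 against 1730 CPM and Batf2 at 565 against 243 CPM, cluster 5 first. Stab2 was lower in cluster 5 (663 against 742 CPM). These cells are outside the endothelial sums, and with all unnamed clusters included the day 4 log2 ratio of Irf1 was 0.63 in place of 0.43. The interferon-induced Oasl1 was 3.36 times as abundant, an excess 1.04 times that of Alb, so this ratio does not part it from the hepatocyte genes. No biological explanation was tested for this cluster.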

How the results depend on the processing

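The alternatives were planned except for the 2 named as added, which were chosen after seeing the data. No paired analysis was run, since each comparison set 1 library against 1 other. Pairing the transplants by day over the 4 libraries was not done. Direction was counted over values at least 1.5-fold apart, each of 1 list or named gene in 1 comparison. The 21 list values counted here are thus not the 21 response lists. Under the planned settings 21 of 21 list values and 120 of 120 gene values kept their direction (119 of 119 gene values with no pseudocount). Exceptions were 20 of 21 list and 116 of 120 gene values with every cluster weighted the same. Others were 20 of 21 list values at the higher expression minimum, and 119 of 120 gene values in the LSEC-like clusters alone. Values less than 1.5-fold apart could cross 0, as the JAK-STAT median did at day 4 (0.029, range -0.024 to 0.309). Over the planned settings the interferon gamma median ranged from 1.83 to 2.502 at day 4 and from 2.07 to 2.39 at day 14, and the Irf1 log2 ratio from 0.27 to 1.10 at day 4 and from 0.45 to 0.94 at day 14. In all, 749 list values and 884 gene values moved past their counting interval with their direction kept, a further 3 and 12 reversed, and 1264 and 1650 did not move. Of gene counts and shares of cells, 36 and 26 moved and 118 and 2 did not. With a median of 1033 UMIs per endothelial-like cell in the syngeneic day 14 library, depth limits low genes most at that day. Unless said otherwise, the cause was not tested. Values below are the interferon gamma medians, their difference between the days, and counts of genes at least 2-fold higher and lower.

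With median of ratios scaling, the day 4 median was 2.24, and the day 14 against day 4 counts were 148 and 286 (allogeneic) and 73 higher (syngeneic). With TMM they were 137 and 305, and 51 and 481. A pseudocount of 5 CPM gave 75 higher genes in the syngeneic pair of days. At a minimum of 50 CPM for genes and 20 for lists, fewer genes were compared. There were 79 lower genes at day 4, 101 lower at day 14, and 124 (allogeneic) and 62 (syngeneic) higher between the days, and the MHC class II difference between the days reversed from 0.93 to -1.94. With no minimum, and so more genes, the counts were 327 and 286 at day 4, 673 and 437 at day 14, 794 and 435 between the allogeneic days and 246 and 474 between the syngeneic days. The day 4 median was 1.83 and its difference between the days 0.42.

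With at least 1000 UMIs per cell, the medians were 2.10 and 2.07, their difference -0.03, and 292 genes were lower between the allogeneic days. With no filter on UMIs, genes or mitochondrial share, the allogeneic days gave 508 and 314 genes. With no doublets removed, the day 4 median was 2.098, the difference 0.17, and 264 genes were lower between the allogeneic days. With 2 times as many removed, the medians were 2.31 and 2.20, the difference -0.11, and the allogeneic days gave 466 and 290.0 genes. Resolution 0.5 gave medians of 2.13 and 2.22, and 502 and 281 genes between the allogeneic days, and resolution 2.0 gave 485 and 288.

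In the LSEC-like clusters alone the medians were 2.13 and 2.39, the difference 0.27, and Rnf43 at day 14 reversed to 0.056. A gate on endothelial markers per cell gave 2.21 at day 14, and 551 and 327 genes between the allogeneic days. With every cell weighted the same, the medians were 2.36 and 2.36, the difference -0.00, and 42 genes were higher between the syngeneic days. With every shared cluster weighted the same (clusters 0, 1, 10 and 14), the medians were 2.502 and 2.11, the difference -0.40, and 134 genes were lower between the syngeneic days. At day 14 Alcam reversed to 1.13, Pmaip1 to -1.17, Tnfrsf10b to -0.65 and Serpine2 to -0.10, and the chemokine difference between the days to -0.15. That setting left out cluster 6, which held 77.7% of the allogeneic day 14 LSEC-like cells. In the syngeneic day 14 library clusters 1 and 14 had only 57 and 60 cells. Over all endothelial-like cells of that library Pmaip1 had 22 UMIs and Serpine2 42, so these reversals rest on few UMIs. With cells thinned to 1000 UMIs the medians were 2.28 and 2.14 and the difference -0.14. That left out 1106 allogeneic and 464 syngeneic cells at day 4, and 417 and 3836 at day 14.

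With the unnamed clusters included (added), the allogeneic days gave 522 and 325 genes, and the transplant counts were 176 and 196 at day 4 and 319 and 164 at day 14. With the syngeneic day 4 library as the control at day 14 (added), which brings in the difference between the days, the counts were 335 and 209 and the median 2.09. Among values at least 1.5-fold apart, direction was kept by 5 of 6 lists and 46 of 53 named genes, and the reversed values at day 14 were -0.05 for the type I interferon list, -0.60 for Irf1, -0.37 for Cxcl10, -0.31 for Vcam1, -0.38 for Socs1, -0.003 for Irf8, -0.94 for Casp4 and -0.17 for Inhbb. Of the lists less than 1.5-fold apart, 4 crossed 0 with this control, the NF-kB and TNF response from 0.44 to -0.32, the p53 response from 0.09 to -0.35, immediate early and heat shock genes from 0.09 to -0.87 and oxidative phosphorylation from 0.09 to -0.06.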

Other observations

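The genes of this part were chosen after their values were seen, and no test was run on them.

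The Wnt ligands Wnt2 and Wnt9b and their enhancer Rspo3, with which endothelium around the central vein sustains hepatocyte zonation, were lower in the allogeneic library at day 14. The whole list of angiocrine and Wnt factors was not lower at that day, with 6 of 17 members higher and 5 lower (median log2 ratio 0.15). In LSEC-like cells 8 of 16 were higher and 1 lower (0.66). Rspo3 was at 560 against 1283 CPM (ratio 0.436, 0.424 to 0.449) and Wnt2 at 260 against 403 CPM (ratio 0.645, 0.617 to 0.675). At day 4 Rspo3 was at 409 against 532 CPM and Wnt2 at 147 against 227 CPM, whereas Wnt9b was higher in the allogeneic library at day 4 (283 against 192 CPM) and lower at day 14 (310.0 against 468 CPM). In the syngeneic libraries cluster 4 held 10032 of 19255 endothelial Rspo3 UMIs at day 4 and 11303 of 13438 at day 14 (3205 and 3302 CPM within it). That cluster had 926 and 1678 cells in the syngeneic libraries and 50 in the allogeneic day 14 library, in which Rspo3 was at 2746 CPM within it. Within it at day 14, Wnt2 was at 565 (452 to 697) against 617 CPM and Wnt9b at 1227 (1058 to 1415) against 1123 CPM. In cluster 10 Wnt2 was at 45.1 against 35.8 CPM and Wnt9b at 91.4 against 52.0 CPM, with overlapping intervals. The lower levels of the Wnt ligands in the summed cells are thus tied to the mix of clusters.

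LSEC markers did not move together. Stab2 was lower in the allogeneic library at both days (506 against 841 and 776 against 1261 CPM), and Clec4g stood at 609 against 1321 CPM at day 4 and 1212 against 1516.7 CPM at day 14. Lyve1, the hyaluronan receptor shared by sinusoidal and lymphatic endothelium, was at 230 against 477 CPM at day 4 and 649 against 250.4 CPM at day 14. The p53 targets Cdkn1a (2041 against 2955 CPM) and Mdm2 (638 against 961 CPM) were lower in the allogeneic library at day 4, while at day 14 they were at 1207 against 988 and 536 against 545 CPM. The adhesion gene Selp was alike at day 4 (885 against 836 CPM) and lower at day 14 (210 against 533 CPM).

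The transplant ratios of the 2 days overlapped. Of 7594 genes compared at both days, 172 were at least 2-fold higher at day 4 and 235 at day 14, and 117 were higher at both, against 5.32 if the lists were independent. Of the lower genes, 135 at day 4 and 123 at day 14, 45 were shared, against 2.19. Across genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.622 and Spearman's rho 0.374.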
